A study of Mus musculus with 6 samples.

How the data were processed

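RNA was measured in differentiated cells of an immortalized mouse podocyte line, in 3 samples of total input RNA and 3 samples of RNA co-precipitated with Staufen2. Per the labels' protocols, cytoplasmic lysates were cleared with protein G beads, incubated with an antibody against Staufen2 and captured on protein G beads, and RNA was isolated from the pulldown and the input. Per the labels' protocols, 100 ng of RNA from either source was amplified with a whole-transcript kit and labelled with biotin for hybridization to arrays. Equal amounts of RNA were thus labelled whatever the yield of the pulldown, so the values compare the make-up of the RNA and not its amount.

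The deposited values were log2 expression values per probe set, 1 column per array, made by RMA per the submitters' processing notes, which also name limma. Versions were not given in the sources used here. RMA as commonly run makes the arrays' distributions alike by quantile normalization, and the array medians of 6.53 to 6.54 differed little. Such scaling takes most RNAs to balance out, so differences are relative to the other RNAs on the array. The table held 35556 probe sets. In the platform's annotation 21789 had 1 gene symbol, 1621 had several and 12146 had no listed gene. Only probe sets with 1 symbol were named. For the 999 genes with more than 1 such probe set the brightest over all 6 arrays was used, and in 21 of them called probe sets went in both directions. This left 19938 genes, of which 19856 matched the reference gene table through their Entrez identifiers and took their gene type and genomic span from it. Spans were used only as a measure of size and no coordinates are given, since the annotation names no genome build.

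Differences are pulldown minus input on the log2 scale, from a linear model with moderated variances (limma 3.58.1 in R 4.3.3, 2-sided, without covariates). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. SEs are the moderated standard errors. An exact permutation test of 3 against 3 samples cannot give a p below 0.10. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation and with the rotation test fry. Replicate numbers were taken as names and not as pairs.

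Before the data were examined, the lists and the rule for the genes named were fixed. Stau1 and Stau2 were named in any case. The 14 largest positive and 14 largest negative differences were named among genes past the test whose groups did not overlap, leaving out symbols of predicted genes, microRNAs, small nucleolar RNAs (Snora and Snord) and receptor families, while other noncoding RNAs were kept, and genes not above the median of all probe sets (6.54) in the higher group. From each list, the 4 members with the smallest adjusted p were eligible. The lists cover podocyte and slit diaphragm genes, actin filaments, focal adhesions, microtubules and motors, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, the proteasome, translation factors, replication-dependent histones, zinc finger genes, extracellular matrix, the endoplasmic reticulum, the cell cycle, small and nuclear noncoding RNA, RNA granules, described Staufen targets, the interferon response, and markers of mesangial, endothelial, tubular and immune cells. A further list is not reported here. Lists defined by symbol patterns can take in members of other function.

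The alternatives planned were a replicate block, an intensity trend in the variances, centring on the brightest probe sets (above their 75th percentile), cyclic loess, a filter on dim genes, array weights, the mean of a gene's probe sets, all probe sets, a test against a 1.2-fold change (treat), the unmoderated statistic, and leaving out each array in turn. Correlations of the differences with transcript length and GC content had been planned and were not run, since the gene table used here gives neither. Genomic span took their place after the data were seen. It includes introns and so is a coarse measure of the size of the RNA.

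The procedure was tested on simulated data, in which 200 of the 19938 genes were moved. Each gene's spread was set to the moderated value that the test itself uses, so the rates found may be favourable. At a log2 difference of 0.25, 90.9% of the moved genes were called, and at 0.5 and 1 all were, with 7 false calls among 201. A list moved by 0.1 was called and none of the other lists was. The simulated genes varied independently and few were moved. The simulation therefore does not test list calls among correlated genes, nor the scaling when many genes differ. Figures were drawn with matplotlib 3.10.9. The depth of an array has no equivalent of a read count, and the number of arrays limits the precision.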

Results

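RNA bound with Staufen2 was compared with total RNA in a differentiated podocyte line. Podocytes are the epithelial cells of the kidney glomerulus whose foot processes and slit diaphragms form part of the filtration barrier, and the cells used here were an immortalized mouse line differentiated in culture. Staufen2 is a double-stranded RNA-binding protein known for its part in mRNA transport in neurons. The data comprised 6 arrays, 3 of input RNA and 3 of RNA co-precipitated from cytoplasmic lysate with an antibody against Staufen2, each labelled from 100 ng of RNA. Array medians lay between 6.53 and 6.54 on the log2 scale. Pearson correlations over all probe sets were 0.998 to 0.999 within a group and 0.982 to 0.983 between groups, and the first principal component, which separated pulldown from input, held 94.2% of the variance. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and the median standard error of a gene's difference was 0.039.

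The comparison asked which transcripts of the podocyte made up a larger or smaller part of the Staufen2-associated RNA than of the input. The largest positive differences included mRNAs of very large proteins, such as Dst and Macf1. Mki67, a protein of the mitotic chromosome surface, stood at 8.34 ± 0.074 in the input and 10.05 ± 0.055 in the pulldown (log2 value, mean ± SD, n = 3), which is 3.28-fold higher. Small structured RNAs gave the largest negative differences. The vault RNA Vaultrc5 went from 10.19 ± 0.062 in the input to 5.80 ± 0.21 in the pulldown, and the Y RNA Rny1 had a log2 difference of -4.05 ± 0.039 (SE). The pulldown values of Vaultrc5 (5.80) and Rny1 (5.39) lie below the median of all probe sets (6.54), where signal can be background, so the sizes of these differences are uncertain. Of 19938 genes, 9705 (48.7%) passed limma's moderated test at an adjusted p under 0.05, of which 6246 were higher in the pulldown and 3459 lower. At least 2-fold differences were found for 332 genes that were higher and 400 that were lower. The higher genes made up 64.4% of the calls, and 52.9% (5127 higher and 4565 lower) after cyclic loess normalization. Under that scaling 188 genes were at least 2-fold higher and 521 at least 2-fold lower. The median difference of all genes was 0.04. In 55.9% of genes the values of both groups did not overlap, against 10% expected by chance for 3 against 3. No pulldown with a control antibody was analysed here, so a higher value describes the RNA recovered relative to the input and not binding to Staufen2 as such.

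Among the 14 largest positive differences, Sh3pxd2a, the podosome scaffold Tks5, was higher by 1.65 ± 0.032 (log2 difference ± SE), and the spectraplakins Dst and Macf1, which link actin filaments to microtubules, were each higher by 1.54, with SEs of 0.032 and 0.028. Cep350, a centrosomal protein, was higher by 1.64 ± 0.046 and the tubulin-binding protein Tppp by 1.61 ± 0.040. Knl1, a scaffold of the kinetochore, was higher by 1.64 ± 0.11. The histone H3 lysine 4 methyltransferases Kmt2c and Kmt2a were higher by 1.57 ± 0.028 and 1.56 ± 0.029. Larp1, an RNA-binding protein that acts on mRNAs of the translation machinery, was higher by 1.62 ± 0.045. The remaining genes were Zfhx4 (1.57), Alpk3 (1.56), Cplane1 (1.56) and the sodium channel gene Scn2a (1.54). Adjusted p-values from limma for these 14 genes lay between 1.9e-07 and 7.2e-06.

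The 14 largest negative differences under the naming rule, which leaves out small nucleolar RNAs (Snora and Snord), comprised noncoding RNAs and mRNAs. Besides Vaultrc5 and Rny1, the Cajal body RNA Scarna17 had a log2 difference of -3.46 ± 0.079 (SE), Rmrp, the RNA of RNase MRP, -3.26 ± 0.069, and Rpph1, the RNA of RNase P, -3.22 ± 0.044. The histone gene H2bc3 and Plac8 both stood at -2.79. Uqcr11 (-2.57) and Ndufa11 (-2.33) encode small respiratory chain subunits, Rps12 (-2.74), Rps13 (-2.55) and Rps21 (-2.29) ribosomal proteins, and Gzme (-2.35, with a pulldown value of 6.28, below the median of all probe sets) a granzyme. Taf1d had a difference of -2.51. Taf1d, Rps12 and Rps13 carry small nucleolar RNAs in their introns, so their probe sets can hold signal of both and their values are uncertain. Stau1, the paralog of Staufen2, was higher by 0.19 ± 0.029 (limma adjusted p = 0.00088), from 11.92 ± 0.027 to 12.11 ± 0.020. The mRNA of Stau2 itself did not pass the test, at -0.02 ± 0.027 (adjusted p = 0.52), and stood at -0.13 (adjusted p = 0.0052) after cyclic loess.

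**Figure D1:**
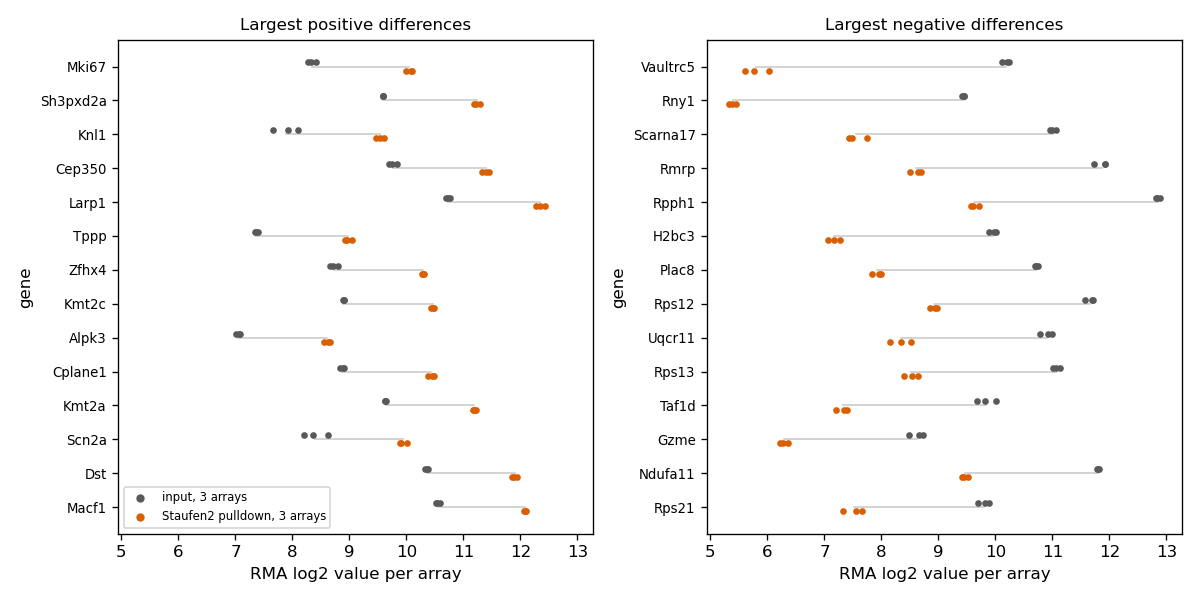
RMA log2 value on each array (x axis) for the 14 genes with the largest positive (left) and the 14 with the largest negative differences (right), with grey points for the 3 input arrays, orange points for the 3 Staufen2 pulldown arrays and a line joining the group means. Symbols of predicted genes, microRNAs, small nucleolar RNAs (Snora and Snord) and receptor families were left out by rule. The groups do not overlap for any gene shown, from Mki67 (difference 1.71) to Macf1 (1.54) and from Vaultrc5 (-4.38) to Rps21 (-2.29).

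Genes were then taken by the 23 lists fixed beforehand. By camera with a preset correlation, 16 lists differed from the other genes, 7 of them higher in the pulldown and 9 lower. With an estimated correlation 7 of these calls held, at much larger adjusted p. Among them were the podocyte and zinc finger lists (camera adjusted p = 0.047 each) and the ribosomal protein list (0.033). The oxidative phosphorylation, histone and small RNA lists stood at 0.018 each.

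Podocyte and slit diaphragm genes were higher as a list (camera adjusted p = 0.00073, and adjusted p = 0.047 with an estimated correlation). Of 39 measured members, 26 were higher, 2 were lower and 11 did not pass, and adjusted over the list alone 26 were higher and 3 lower. The median log2 difference was 0.34. Vegfa, the growth factor that podocytes supply to the glomerular endothelium, was higher by 0.97 ± 0.030 (SE), the junction scaffolds Magi1 and Tjp1 (ZO-1) by 0.84 ± 0.027 and 0.84 ± 0.028, and the actin-binding protein anillin, Anln, by 0.77 ± 0.028. The members named next were chosen after their values were seen. Fat1 (0.50), Synpo (0.48), Cd2ap (0.43), Kirrel3 (0.43) and Podxl (0.32) were also higher, and Coq6 (-0.81) and Pdss2 (-0.26), enzymes of coenzyme Q synthesis, were the 2 lower members. Kirrel did not pass (0.03, limma adjusted p = 0.35), at a level of 11.34 in the input. Nphs1 (adjusted p = 0.091), Kirrel2 (0.11) and Ptpro (0.75) did not pass either, but their input values of 6.30, 6.54 and 6.10 lay near or below the median of all probe sets (6.54), as did that of Podxl (6.04), so little can be read from them.

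Actin filament genes did not differ from other genes as a list (adjusted p = 0.35, and adjusted p = 0.28 with an estimated correlation), although 40 of 77 members were higher and 17 lower, with 20 not past the test, and 42 and 18 adjusted over the list alone. Supervillin, Svil, was higher by 1.34 ± 0.026 and the actin nucleator Cobl by 1.00 ± 0.025, while the monomer-binding thymosin Tmsb10 was lower, at -1.72 ± 0.045, as was Brk1, a small subunit of the WAVE complex, at -0.87 ± 0.026.

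Focal adhesion and integrin genes had a median of 0.16 (adjusted p = 0.0093, and adjusted p = 0.13 with an estimated correlation), with 28 of 53 members higher, 6 lower and 19 not past the test, and the same counts adjusted over the list alone. The talins Tln2 and Tln1, which join integrins to actin, were higher by 1.51 ± 0.032 and 0.79 ± 0.034, the laminin receptor subunit Itga6 by 0.88 ± 0.034 and the adaptor Crkl by 0.68 ± 0.027. The call of this list also ended after cyclic loess (adjusted p = 0.071) and among genes above the median level (adjusted p = 0.057). Microtubule and motor genes were higher (median 0.37, adjusted p = 4.4e-05, and adjusted p = 0.086 with an estimated correlation), with 45 of 66 members higher, 9 lower and 12 not past, and 46 and 9 adjusted over the list alone. Map1b, a microtubule-associated protein, was higher by 1.06 ± 0.027, and the kinesins Kif13a and Kif23 by 1.12 ± 0.031 and 1.11 ± 0.031.

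**Figure D2:**
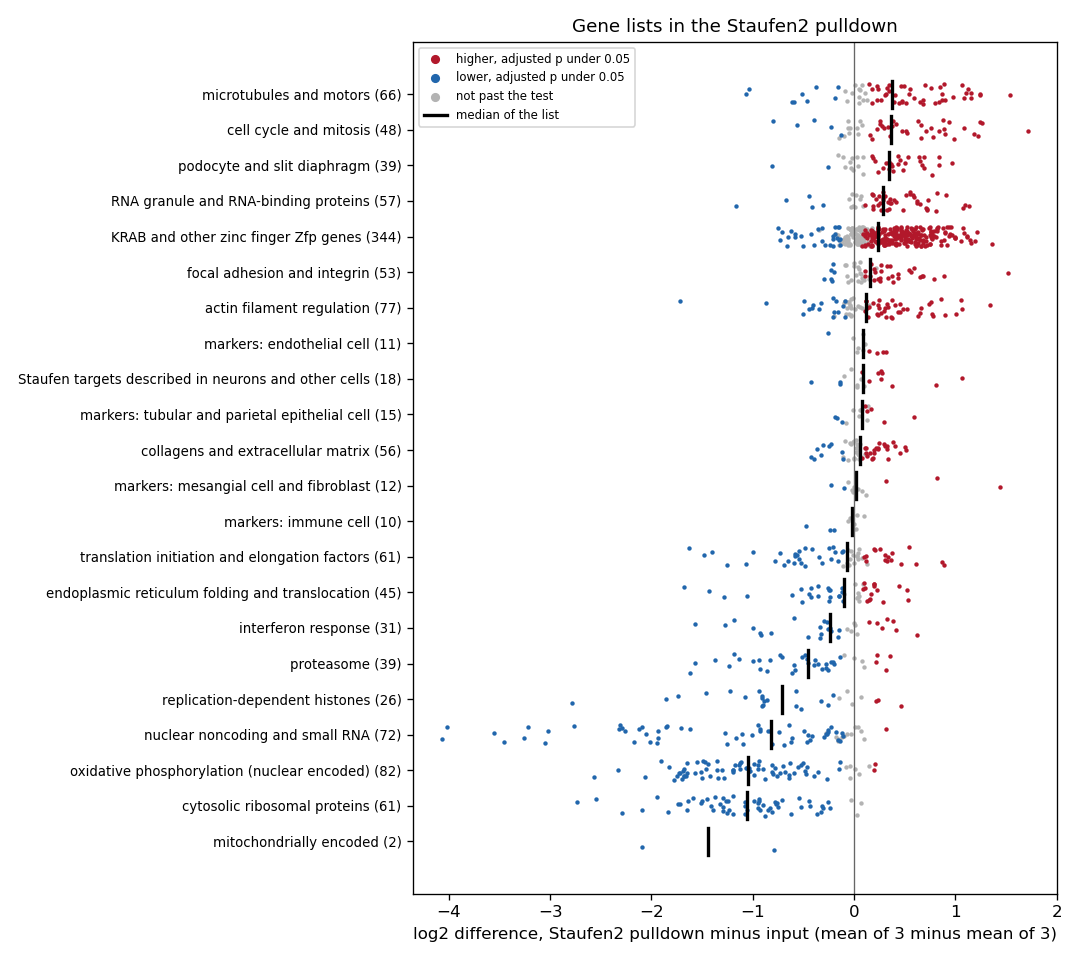
Log2 difference of each measured gene (x axis, mean of 3 pulldown arrays minus mean of 3 input arrays) in each list reported (y axis, number of measured genes in parentheses), with points coloured by the limma call and black bars at list medians. Medians run from -1.44 for the mitochondrially encoded genes to 0.37 for microtubules and motors; that of the mesangial markers (0.02) turns negative (-0.02) when arrays are centred on their brightest probe sets.

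Cell cycle genes were higher (median 0.36, adjusted p = 0.00026, and adjusted p = 0.053 with an estimated correlation), with 33 of 48 members higher, 5 lower and 10 not past, and 33 and 6 adjusted over the list alone. Besides Mki67, the mitotic kinesin Kif11 was higher by 1.24 ± 0.038, the G1 cyclin Ccnd1 by 0.89 ± 0.028 and the spindle factor Tpx2 by 0.76 ± 0.029. Zinc finger genes with Zfp symbols, many of which encode KRAB repressors, were higher as a list (median 0.24, adjusted p = 2.2e-06), with 212 of 344 members higher, 28 lower and 104 not past, and 221 and 29 adjusted over the list alone. Zfp106 was higher by 1.16 ± 0.039, Zfp462 by 1.15 ± 0.028 and Zfp407 by 1.05 ± 0.031. Genes of RNA granules and RNA-binding proteins were higher (median 0.29, adjusted p = 2.6e-05, and adjusted p = 0.053 with an estimated correlation), with 42 of 57 higher, 5 lower and 10 not past, the same counts as adjusted over the list alone. Tnrc6a, the scaffold of microRNA silencing, was higher by 1.13 ± 0.027 and the exonuclease Xrn1 by 0.91 ± 0.031, while Ybx1 was lower, at -0.67 ± 0.025. Zbp1 of this list, also lower at -1.17 ± 0.040, is the symbol of the Z-nucleic acid sensor and not of the zipcode-binding protein.

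Ribosomal protein mRNAs were lower in the pulldown, with none of 61 members higher, 58 lower and 3 not past, and the same counts adjusted over the list alone. Their median of -1.06 corresponds to 2.08-fold lower (camera adjusted p = 1.1e-32, and adjusted p = 0.033 with an estimated correlation). Rpl26 stood at -1.95 ± 0.045, Rps7 at -1.83 ± 0.039 and Rps4x at -1.32 ± 0.028. Nuclear-encoded oxidative phosphorylation genes were lower to a similar degree (median -1.05, adjusted p = 1.2e-34, and adjusted p = 0.018 with an estimated correlation). Of 82 members 2 were higher, 74 lower and 6 not past, and 3 and 74 adjusted over the list alone. Ndufb9 of complex I stood at -1.91 ± 0.036 and the ATP synthase genes Atp5o and Atp5g1 at -1.68 ± 0.033 and -1.50 ± 0.031. Both measured mitochondrially encoded mRNAs were lower, ND3 at -2.10 ± 0.044 and COX2 at -0.79 ± 0.054 (list adjusted p = 0.0043, and adjusted p = 0.14 with an estimated correlation), also adjusted over the list alone.

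Proteasome subunits were lower (median -0.46, adjusted p = 4.0e-12, and adjusted p = 0.053 with an estimated correlation), with 4 of 39 higher, 31 lower and 4 not past, the same counts as adjusted over the list alone. The core subunits Psmb6, Psmb1 and Psma6 stood at -1.62 ± 0.057, -1.37 ± 0.034 and -1.24 ± 0.026. Translation initiation and elongation factors went both ways (median -0.07, adjusted p = 0.00026, and adjusted p = 0.12 with an estimated correlation), with 17 of 61 higher, 29 lower and 15 not past, the same counts as adjusted over the list alone. The eIF3 subunits Eif3i, Eif3k, Eif3f and Eif3m stood at -1.48, -1.40, -1.25 and -0.99. Of 26 replication-dependent histone genes, whose mRNAs mostly end in a stem-loop in place of a poly(A) tail, 3 were higher, 19 lower and 4 did not pass (median -0.72, adjusted p = 1.6e-09), and adjusted over the list alone 3 were higher and 20 lower. H2ac15 stood at -1.86 ± 0.064, H4c14 at -1.23 ± 0.035 and H2bc9 at -0.91 ± 0.028. These genes have near-identical copies, so single members are uncertain. Of 72 nuclear noncoding and small RNAs, 1 was higher, 58 were lower and 13 did not pass (median -0.82, adjusted p = 6.6e-22), and adjusted over the list alone 2 were higher and 63 lower. The small nucleolar RNAs Snora52 and Snord35b stood at -4.06 ± 0.044 and -3.03 ± 0.043, and the size of the latter is uncertain because its pulldown value (5.57) lies below the median of all probe sets.

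Endoplasmic reticulum folding and translocation genes had a median of -0.10 (adjusted p = 0.0079, and adjusted p = 0.19 with an estimated correlation), with 15 of 45 higher, 22 lower and 8 not past, also when adjusted over the list alone. The lower members included Ssr4 at -1.68 ± 0.032 and Sec61b at -1.43 ± 0.053, small subunits of the translocon, and the signal recognition particle proteins Srp14 at -1.28 ± 0.062 and Srp9 at -0.62 ± 0.029. Interferon response genes were lower (median -0.24, adjusted p = 4.1e-05, and adjusted p = 0.053 with an estimated correlation), with 7 of 31 higher, 19 lower and 5 not past, also when adjusted over the list alone. Psmb10 and Psmb9, subunits of the immunoproteasome that belong to the proteasome list as well, stood at -1.57 ± 0.055 and -0.93 ± 0.036, Isg20 at -1.27 ± 0.041 and Irf7 at -0.99 ± 0.038. Collagen and extracellular matrix genes did not differ as a list (median 0.05, adjusted p = 0.47, and adjusted p = 0.67 with an estimated correlation), with 24 of 56 higher, 9 lower and 23 not past, and 24 and 10 adjusted over the list alone. Mmp14 was higher by 0.50 ± 0.035, Postn by 0.45 ± 0.038, Timp3 by 0.40 ± 0.026 and Col12a1 by 0.38 ± 0.029.

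Transcripts described as Staufen targets in neurons and other cells did not differ from other genes as a list (median 0.09, camera adjusted p = 0.35, and adjusted p = 0.38 with an estimated correlation). Of 18 measured, 9 were higher, 3 lower and 6 did not pass, also when adjusted over the list alone. Besides Map1b, Kank2 was higher by 0.81 ± 0.034 and Jun by 0.37 ± 0.039, while Rab13 was lower, at -0.42 ± 0.040. Markers of other kidney and blood cells did not differ as lists either. Of 12 mesangial and fibroblast markers 3 were higher and 2 lower (adjusted p = 0.94), of 11 endothelial markers 4 and 1 (adjusted p = 0.35), of 15 tubular and parietal markers 5 and 3 (adjusted p = 0.90) and of 10 immune markers 0 and 3 (adjusted p = 0.11), with the same counts adjusted over each list alone. The smooth muscle myosin Myh11 was higher by 1.44 ± 0.034, Gata3 by 0.82 ± 0.077, Cubn by 0.59 ± 0.064 and Ehd3 by 0.31 ± 0.030. Cd14 was lower, at -0.48 ± 0.082.

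The difference between pulldown and input followed the genomic span of the gene. Across 18556 protein-coding genes Spearman's rank correlation was 0.36 for the mean of the 3 pulldown arrays and 0.35 to 0.36 for each array. It was 0.48 across the 11630 coding genes above the median level of all probe sets. Genes are not independent replicates, so no p is given. Among the latter genes, 1148 of the 1530 spanning over 100 kb were higher and 120 lower, whereas 81 of the 583 spanning 1 to 3 kb were higher and 300 lower. Of 53 small nucleolar RNA genes 44 were lower and 0 higher. Of 297 microRNA genes 17 were higher and 18 lower, and most did not pass the test (median 0.00015, quartiles -0.047 and 0.043).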

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

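The sorting of unnamed probe sets was chosen after the data were seen. Some probe sets outside the named genes had more signal in the pulldown than in the input arrays, although more had less. Of 12146 probe sets without a listed gene, 1420 were higher and 2180 lower at a limma adjusted p under 0.05, with a median difference of -0.02 over all of them, and 140 were at least 2-fold higher and 343 at least 2-fold lower. All 140 lay above the median of all probe sets in the pulldown. The largest of these differences was 2.05, from 8.88 in the input to 10.93 in the pulldown, which exceeds that of any gene tested. Of 1621 probe sets listed with several genes, 6 were at least 2-fold higher and 185 at least 2-fold lower. Groups of 3 arrays are too small for a test of single outlying samples.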

How the results depend on the processing

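The genomic span correlations (0.36 for all coding genes and 0.48 among those above the median level) were added after the data were seen, and the other alternatives were planned. Called genes numbered 8406 to 9900 under the intensity trend, the scalings, the filter on dim genes, array weights, the mean of probe sets and the unmoderated statistic, and 8873 to 9288 when single arrays were left out. Lists passing camera numbered 16 with each array left out, and 15 after cyclic loess and among genes above the median level. Same-numbered arrays did not deviate together (correlations 0.0064, 0.041 and -0.052), and the replicate block gave 9714 genes and 16 lists. After cyclic loess 8554 of the 9705 called genes were called again, and in all 188 genes were at least 2-fold higher and 521 at least 2-fold lower. Testing all probe sets gave 8104 higher (55.7% of the calls), 6441 lower, 599 at least 2-fold higher and 1107 at least 2-fold lower. More features were tested, but their make-up differed as well. Of 1621 probe sets with several genes 185 were at least 2-fold lower, against 400 of 19938 genes. The cause of the changed counts was not tested. The treat test, by its stricter null, called 4856 genes, 3034 higher and 1822 lower.

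For focal adhesion the adjusted p was 0.0708 after cyclic loess and 0.0570 among genes above the median level (the cause was not tested), with 0.0082 to 0.017 over left-out arrays. Some list medians moved with the scaling. After cyclic loess focal adhesion went from 0.16 to 0.067, actin from 0.12 to 0.033 and described Staufen targets from 0.09 to 0.049. The podocyte list went from 0.34 to 0.24, the cell cycle from 0.36 to 0.26 and RNA granules from 0.29 to 0.19. Camera still called these 3 lists then (adjusted p = 0.0014, 0.00073 and 0.00010). Translation factors went from -0.07 to -0.18 and the endoplasmic reticulum from -0.10 to -0.20. The extracellular matrix went from 0.05 to 0.0033, and camera's direction turned to lower (adjusted p = 0.75). With an estimated correlation 7 lists passed, and the cause of the lost calls was not tested. Adjusted p was then 0.128 for focal adhesion, 0.0860 for microtubules, 0.137 for mitochondrially encoded genes, 0.115 for translation factors, 0.185 for the endoplasmic reticulum, and 0.0534 each for the proteasome, cell cycle, RNA granule and interferon lists. Fry, which does not compare a list with other genes, passed all 23 lists, adding actin (1.95e-06), extracellular matrix (0.00116), described Staufen targets (2.09e-05) and the mesangial (0.00203), endothelial (2.97e-04), tubular (0.00844) and immune (0.00191) markers. In either direction it gave 4.48e-08, 3.71e-07, 2.99e-07, 9.88e-07, 3.31e-05, 4.78e-06 and 4.30e-04 for these.

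Of 1660 pairs of a named gene and a setting, 1643 kept call and sign, 16 lost the call, 1 gained it (Stau2 after cyclic loess) and 0 reversed. Apart from treat, the losses were of Emcn (-0.23, adjusted p = 0.051 without pulldown replicate 1, and 0.068 with the unmoderated statistic). Planned correlations with transcript length and GC content were not run. Signal near background limits what the arrays show for dim genes.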

Other observations

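The families below, the examples from the actin, microtubule and small RNA lists, the limit to genes above the median level and the test on 3 lists were chosen after the data were seen. For the comparison with lists matched on span and level, an expectation was written down beforehand for the podocyte, zinc finger, ribosomal protein, oxidative phosphorylation and Staufen target lists, and none for the others.

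Further gene families, 11 in all, were taken by symbol after the values had been seen, when their members Kmt2a, Kmt2c and Cep350 had already been named. Camera was run on all 11, and its p-values are left out because the families were chosen on the same values. The counts by limma and the medians are a description. Of 77 mitochondrial ribosomal protein genes 70 were lower and 1 higher (median -0.73), with Mrpl14 at -2.14 ± 0.082 (SE). Of 25 spliceosomal Snrp and Lsm genes 17 were lower and 4 higher (median -0.49). All 17 chromatin regulators of the Kmt2, Chd and Nsd families were higher (median 1.02), among them Nsd1 at 1.42 and Chd6 at 1.37. Of 18 HECT and Ubr ubiquitin ligases 17 were higher and 0 lower (median 0.64), with Hectd4 at 1.34, and of 35 ubiquitin-conjugating enzymes 9 were higher and 16 lower (median -0.10). Centrosomal Cep genes were higher in 27 of 33 cases and lower in 0 (median 0.42), and Dock exchange factors were higher in 8 of 10 and lower in 0 (median 0.61). Of 23 genes of homologous recombination and translesion repair 16 were higher and 2 lower (median 0.54), with Polq at 1.46 and Rev3l at 1.41. Vacuolar ATPase subunits (2 of 21 higher, 10 lower) and S100 genes (1 of 13 higher, 7 lower) had medians of -0.13 and -0.10. After cyclic loess these medians were -0.23 and -0.18. Of 323 solute carriers 80 were higher and 52 lower, and theirs was the only family median to change sign with the scaling, from 0.04 to -0.0043 when centred on the brightest probe sets.

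Members of the cytoskeletal lists went both ways. In the actin list the Arp2/3 subunit Arpc4 stood at -0.49 and the light chain Myl6 at -0.44, against 1.05 for the formin Diaph3 and 0.78 for the heavy chain Myh10. In the microtubule list Tuba4a stood at -1.03 and Tuba1a at -0.52, against 0.84 for the dynein heavy chain Dync1h1. Malat1, a nuclear RNA, stood at -2.17.

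Small nucleolar RNAs, ribosomal protein and oxidative phosphorylation genes were lower and coding genes of wide span more often higher. Most microRNA genes did not pass the test (17 higher and 18 lower of 297). Recovery by RNA size, for which only genomic span was at hand, is a candidate explanation. Unlisted coding genes spanning under 3 kb had a median of 0.0141 (2254 genes, 195 higher and 315 lower) against 0.0196 to 0.0258 in the central 95% of 10000 sets matched on level. The 599 above the median level had -0.0975 (quartiles -0.63 and 0.062) against 0.058 to 0.10. Families outside the lists that were mostly lower, such as mitochondrial ribosomal proteins (70 of 77), were not taken out. The comparison therefore cannot separate size from what a gene encodes. A brightness trend left in the deposited values was tested by how much of a gap cyclic loess leaves. Cyclic loess was run on the RMA values and cannot undo a normalization already in them, so an effect of that normalization stays open. The tests of a trend differ. Cyclic loess kept 25.4% of the small gap of -0.039 between short and wider unlisted genes at all levels, the test first written down. A trend may thus account for most of that gap. Cyclic loess kept 93.3% of the gap of -0.20 between short and wider unlisted genes above the median level. It kept 107% of the gap of -1.03 between the 215 members of 3 lists and all other genes. These were the ribosomal protein, oxidative phosphorylation and small RNA lists. Both gaps were chosen later. The gap of -0.20 holds no member of the lists, so it says nothing of the cause of their shift. Cyclic loess moved the medians of these lists little and downward, to -1.165 for ribosomal proteins, -1.157 for oxidative phosphorylation and -0.861 for small RNAs. The 107% thus argues only against a brightness trend of the kind that cyclic loess removes as the whole cause for these lists. Binding of particular mRNAs by Staufen2 stays open, since the described targets stood at the 86.4th percentile of lists matched on span and level and no control pulldown was analysed. Whether a selection by size would arise in Staufen2 itself, on the beads or in the amplification was not tested, and genomic span is a coarse stand-in for transcript length.

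Gene span and array level alone were tested as an explanation of 4 list shifts. Podocyte genes (median 0.34) lay above the central 95% of matched lists, whose median was 0.172, and zinc finger genes (0.24) above theirs (0.0432). Ribosomal protein genes (-1.06) lay below theirs (-0.286) and oxidative phosphorylation genes (-1.05) below theirs (-0.119). Span and level thus did not account for the whole shift of these lists, while the length of the mature RNA, which may differ from span, was not tested. The same comparison was made for 21 lists, of which 11 lay outside the range. These include the extracellular matrix (0.05, percentile 1.3) and immune marker lists (-0.02, percentile 1.24), which camera had not called and which lay below their matched lists. Of the 14 among them that camera had called, 5 lay inside it, namely focal adhesion (percentile 55.1), endoplasmic reticulum (23.1), RNA granule (95.3), interferon (5.46) and translation factor genes (2.73).

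The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 9705 genes and 16 lists, and 1 of 10 splits, the real one, reached each count. The highest of the other splits called 0 genes by limma, with at most 154 at an unadjusted p under 0.05 against 10680, and 11 lists. Every other split mixes pulldown and input arrays in both groups. Their difference then adds to the spread within groups, so few gene calls could arise, and part of it stays between groups. The other splits are therefore no measure of the calls that arise without a difference.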
